A study of Arabidopsis thaliana with 24 samples.

How the data were processed

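The series holds RNA-seq of whole seedlings of Arabidopsis wild type (Col) and ino80-5, at 21 °C and after 1 h or 12 h at 27 °C, with 3 libraries in each of 8 groups. RNA was taken with the Takara Minibest plant kit and libraries made with the NEBNext Ultra RNA kit, per the labels, which state neither poly(A) selection nor strandedness. TPM values were computed by the authors before the tables were deposited, with 1 column per library and 1 table for each time. The submitters' processing notes name fastp 0.20.1, HISAT2 2.1.10, HTSeq 0.11.2, DESeq2 1.26.0 and the build TAIR10, without their role or order. The gene lengths behind the TPM, the filter that chose the genes of each table and the strand setting are not stated. The header of each table has 1 name fewer than the columns, with no name over the gene identifiers, so names were read as those of the value columns in order. Groups and replicate numbers were taken from the labels.

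The tables hold 23390 genes at 1 h and 23282 at 12 h, all Araport11 identifiers, of which 23241 and 23135 were found in the reference gene table of assembly TAIR10.1. The 149 and 147 others were organelle genes. TAIR10.1 served for symbols, transcript lengths and the order of genes, and no coordinates are given because its name differs from that in the labels. The number of fragments per library was estimated from the steps between small values of TPM times length. Between replicate pairs the variance was 1.3 to 2.65 times the counting variance at 1 h and 1.52 to 2.65 times at 12 h.

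Each table was fitted alone, since 1 h and 12 h were scaled apart and may differ in time of day, so times are compared only by overlaps of calls. Genes with a TPM of at least 1 in at least 3 of 12 libraries were tested, 19190 at 1 h and 19578 at 12 h. The fit was limma 3.58.1 on log2(TPM + 1) with 4 group means per table and empirical Bayes moderation with a trend. There were 5 two-sided contrasts per table, namely temperature in Col, temperature in ino80, genotype at 21 °C, genotype at 27 °C and the genotype by temperature interaction. P-values were adjusted by Benjamini-Hochberg over the tested genes, and a gene was called at adjusted p < 0.05. A fold change of a low gene is drawn toward 0 by the added 1.

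The 18 gene lists with 350 entries were written from general knowledge before the data were examined. For 14 entries whose symbol holds a point, the symbol was replaced by that of the reference table after results were seen, with the same loci, so LHCB1.1 and LHCB1.2 are called CAB2 and CAB3. The lists cover INO80, SWR1 and H2A.Z subunits, transcription elongation and H3K4 methylation, thermomorphogenesis and shade growth, thermosensory and photomorphogenesis regulators, auxin, brassinosteroid and gibberellin, heat shock, circadian clock, flowering time, photosynthesis and chlorophyll, flavonoids, cold, salicylic acid defence, DNA damage, ethylene, and markers of roots, seed maturation and floral organs. Each list with at least 5 tested members was tested by camera with its preset correlation of 0.01, two-sided, with Benjamini-Hochberg over the lists of a contrast, so 17 were tested. PI was the only floral organ marker tested. Counts adjusted over the list alone used the list's members only. Further lists, chosen after the results were seen, are given among the other observations.

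Genes named in the text come from a rule written before the data were examined. It takes INO80 and the members of its list in every comparison, and up to 8 rising and 8 falling genes with the largest changes per contrast. The latter had to be called, reach a mean TPM of 5 in the higher group and have all 3 libraries of a group beyond all 3 of the other, which chance gives for 10 percent of genes. For the interaction the sign had to hold without each library. The rule adds up to 4 members per list with the largest moderated statistic, and PIF4, YUC8, IAA19, IAA29, FT, HSP70-4, FLC, HSFA2, SAUR19 to SAUR24, HTA8, HTA9 and HTA11 in every temperature comparison. The text names a choice of these genes. Of 184 nuclear genes named there, 21 overlap another annotated gene by at least 200 bp, which are LHCB6, PnsB1, BES1, APR2, SARD1, CKX5, WRKY33, COR15B, PIE1, LUX, HTA4, XTH15, GH9B15, EEN, FLC, AT5G12110, RVE1, EBF2, ATX5, HGO and PIF7. Their values are uncertain because the strand use is not stated.

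Overlaps of calls were tested by Fisher's exact test, two-sided. The share of the Col response kept in ino80 used genes called in Col without 1 replicate and measured in the left-out one. The order of genes along chromosomes was tested with 10000 permutations. The fit was tested on simulated data with each gene's spread pooled over the groups and 200 genes changed. Of changes of 1 log2 unit, 95.5 percent were recovered in a temperature contrast at 1 h and 12 h. The interaction recovered 80.6 and 82.1 percent. Of changes of 0.5 log2 units the interaction recovered 37.3 and 23.9 percent. Depth, library number and the share of changed genes, far below that of temperature calls, were not varied. False calls were 7 of 184 and 11 of 175 calls in the temperature contrasts, and 10 of 155 and 7 of 144 in the interaction, at 1 h and 12 h. A true share kept of 0.8 came out as 0.786 at 1 h and 0.793 at 12 h, and a share of 1 as 0.985 and 0.992.

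Alternatives were pseudocounts of 0.1 and 5, no filter, a mean TPM of at least 5, rescaling by the median of ratios, quantile normalization, organelle genes left out, a replicate block, fits of the compared groups alone, robust moderation, an absolute log2 fold change of at least 1, each library left out, and camera with an estimated correlation or fry. All 24 libraries were used. FT was not tested, IAA29, SAUR19 and SAUR22 were tested at 12 h only, and reads, protein and chromatin data were not analysed here. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and in R 4.3.3.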

Results

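RNA of whole Arabidopsis thaliana seedlings was sequenced in 24 libraries, which fell into 8 groups of 3 replicates. Wild-type Columbia (Col) and the mutant ino80-5, called ino80 here, grew for 7 days at 21 °C in short days. They then stayed at 21 °C or moved to 27 °C for 1 h or 12 h. INO80 is the ATPase of a chromatin-remodelling complex, and the series asked whether it acts in thermomorphogenesis, the growth response to mild warmth. Each library held an estimated 13.2 to 25.2 M fragments at 1 h and 13.5 to 15.5 M at 12 h. A TPM of 0.0675 to 0.1305 at 1 h and 0.1078 to 0.1274 at 12 h stood for 1 fragment in a gene of 1 kb. Replicates correlated at r = 0.9928 to 0.9965 across genes at 1 h and 0.9903 to 0.9952 at 12 h, where genes are not independent replicates. The labels do not say whether replicates came from separate cultures, so each p-value of a gene's change measures the spread between samples. Changes are log2 fold changes ± SE from limma with n = 3 per group, and each adjusted p is two-sided.

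INO80 (AT3G57300), the gene mutated in ino80, was lower in the mutant in all 4 comparisons of the genotypes. At 1 h its level was 18.7 ± 1.65 TPM (SD, n = 3) in Col at 21 °C and 13.5 ± 1.18 in ino80, and at 27 °C it was 15.8 ± 1.3 and 11.3 ± 0.368. The differences were -0.44 ± 0.08 (adjusted p = 0.00078) and -0.45 ± 0.08 (adjusted p = 0.00058). At 12 h Col held 21.6 ± 1.41 TPM at 21 °C against 16.8 ± 0.569 in ino80, and at 27 °C 43.4 ± 5.74 against 28.7 ± 5.15. These differed by -0.34 ± 0.12 (adjusted p = 0.046) and -0.59 ± 0.12 (adjusted p = 0.0019). Without any 1 of its 6 libraries (Col or ino80 at 21 °C, replicates 1, 2 and 3) the first of these, at 21 °C and 12 h, had an adjusted p between 0.0524 and 0.126, with changes from -0.39 to -0.31. The other 3 differences passed the threshold without each of their libraries. The place of the insertion in the gene was not used here, so a value over the whole gene does not measure which part is transcribed. INO80 itself rose with warmth at 12 h in both genotypes, by 0.97 ± 0.12 in Col and 0.72 ± 0.12 in ino80. At 1 h its change with warmth was -0.22 ± 0.08, adjusted p = 0.052 in Col and -0.24 ± 0.08, adjusted p = 0.043 in ino80. The value in Col did not pass, but did under 7 of the alternatives. They are a pseudocount of 5, a mean TPM of at least 5, median-of-ratios scaling, quantile normalization, the replicate block, robust eBayes and leaving out Col 21C replicate 1. The value in ino80 had an adjusted p of 0.0512 with a pseudocount of 5, 0.0572 with no filter on low TPM, 0.0671 without ino80 21C replicate 1, 0.171 without ino80 21C replicate 2, 0.126 without ino80 27C replicate 1, 0.0674 without ino80 27C replicate 2 and 0.0809 without ino80 27C replicate 3.

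Among the other subunits of INO80 and of the related SWR1 complex, and the H2A.Z histones that SWR1 deposits, HTA11 was lower in ino80 at 1 h at 21 °C (-0.64 ± 0.10, adjusted p = 0.00015) and at 27 °C (-0.88 ± 0.10, adjusted p = 7.9e-06). HTA8 (-0.43 ± 0.11) and HTA9 (-0.18 ± 0.05) were lower and SWC2 (0.39 ± 0.08) higher at 21 °C, and PIE1 was lower at 27 °C (-0.34 ± 0.09). At 12 h HTA11 was lower at 21 °C (-0.28 ± 0.07, adjusted p = 0.01), and its adjusted p was 0.0518 without ino80 21C replicate 2. At 21 °C and 1 h ARP5 was higher (0.32 ± 0.09, adjusted p = 0.016), with adjusted p of 0.0677 without Col 21C replicate 1 and 0.0704 without ino80 21C replicate 2. At 27 °C and 1 h ARP5 was higher (0.28 ± 0.09, adjusted p = 0.028). Its adjusted p was 0.051 without Col 27C replicate 2, 0.114 without Col 27C replicate 3, 0.109 without ino80 27C replicate 1 and 0.0641 without ino80 27C replicate 3. HTA8 was lower (-0.32 ± 0.11, adjusted p = 0.035), with adjusted p of 0.056 with no filter on low TPM, 0.0545 under median-of-ratios scaling, 0.0521 without Col 27C replicate 1, 0.0947 without Col 27C replicate 2, 0.0878 without Col 27C replicate 3, 0.161 without ino80 27C replicate 2 and 0.094 without ino80 27C replicate 3. RVB2A was lower too (-0.15 ± 0.06, adjusted p = 0.044), and this p was 0.0637 under median-of-ratios scaling, 0.145 without Col 27C replicate 1, 0.0609 without Col 27C replicate 2, 0.0793 without Col 27C replicate 3, 0.0978 without ino80 27C replicate 1 and 0.154 without ino80 27C replicate 2. At 12 h EEN was lower at 21 °C (-0.56 ± 0.17, adjusted p = 0.024), with adjusted p of 0.0504 with a pseudocount of 5, 0.113 without Col 21C replicate 2, 0.0824 without ino80 21C replicate 1 and 0.0621 without ino80 21C replicate 3. HTA4 was lower there as well (-0.69 ± 0.22, adjusted p = 0.032), with adjusted p of 0.0541 with no filter on low TPM, 0.144 without Col 21C replicate 3, 0.15 without ino80 21C replicate 2 and 0.0555 without ino80 21C replicate 3. ARP5 was higher at 27 °C (0.27 ± 0.09, adjusted p = 0.036), with adjusted p of 0.0978 under median-of-ratios scaling, 0.0914 under quantile normalization, 0.0552 with the replicate block, 0.114 without Col 27C replicate 1, 0.0815 without Col 27C replicate 2, 0.144 without ino80 27C replicate 1 and 0.0589 without ino80 27C replicate 2. Of the 19 members with INO80 included, 6 and 6 passed at 1 h, and 4 and 2 at 12 h, at 21 °C and 27 °C. Those that did not pass changed by -0.37 to 0.14 and -0.29 to 0.18 at 1 h, and by -0.28 to 0.22 and -0.47 to 0.36 at 12 h.

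**Figure D1:**
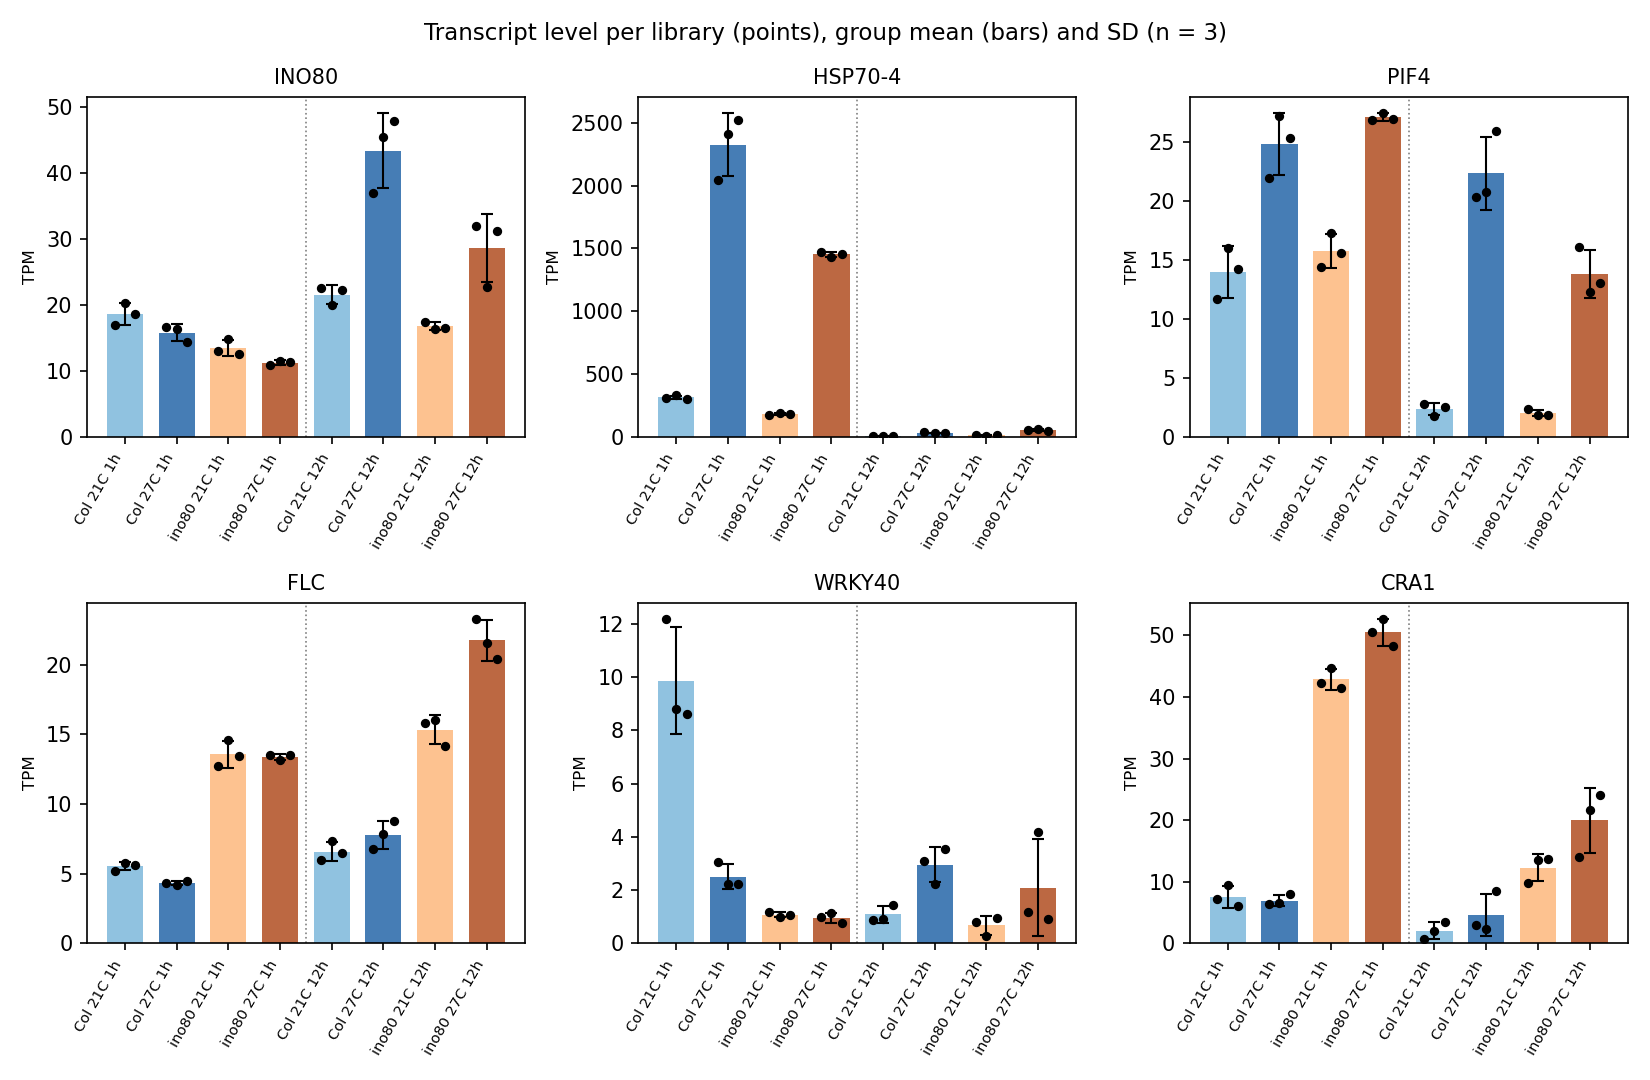
TPM of INO80, HSP70-4, PIF4, FLC, WRKY40 and CRA1 in every library (points) of the 8 groups, with the group mean (bars) and SD (lines, n = 3); the vertical axis starts at 0 and differs between panels. PIF4 at 12 h rose from 2.37 to 22.3 TPM in Col and from 2.05 to 13.8 TPM in ino80.

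The first comparison asked which transcripts wild-type seedlings change within 1 h at 27 °C. Chaperone transcripts were among those that rose most. The peptidyl-prolyl isomerase AT5G48570 rose by 3.69 ± 0.08, HSP90.1 by 3.30 ± 0.08, the small heat shock protein AT5G51440 by 3.25 ± 0.10 and HSP17.8 by 3.16 ± 0.09. HSP70-4 rose from 316 ± 13.5 to 2326 ± 253 TPM (SD, n = 3), a change of 2.87 ± 0.06, and the heat shock factor HSFA2 by 2.70 ± 0.08. The expansin EXPA16 (3.24 ± 0.09) and the growth regulator PIF4 (0.79 ± 0.10, adjusted p = 1.7e-05) rose, PIF4 from 14.0 ± 2.2 to 24.8 ± 2.62 TPM.

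The gibberellin inactivation genes GA2OX2 (-2.78 ± 0.11) and GA2OX8 (-2.08 ± 0.11) fell, while the gibberellin synthesis gene GA3OX1 rose (1.83 ± 0.11). Also falling were APR1 (-2.76 ± 0.08), ATSDI1 (-2.61 ± 0.12), SHM7 (-2.36 ± 0.08) and LSU2 (-2.71 ± 0.13). The growth genes PIF5 (0.66 ± 0.06), IAA19 (0.65 ± 0.13) and CKX5 (0.96 ± 0.12) rose and TAA1 (-0.64 ± 0.08) and BBX18 (-0.81 ± 0.05) fell. Of the 13 genes fixed by name that were tested, 4 rose (PIF4, IAA19, HSP70-4 and HSFA2) and 2 fell, FLC (-0.29 ± 0.08) and HTA9 (-0.16 ± 0.05). The 7 that did not pass, YUC8 and the SAUR genes among them, changed by -0.27 to 0.20. IAA29, FT, SAUR19 and SAUR22 were not tested at 1 h. The light signalling genes HY5 (-1.17 ± 0.09) and HYH (-1.13 ± 0.06), the clock genes GI (-1.25 ± 0.06), PRR5 (-1.54 ± 0.12) and LHY (-0.86 ± 0.05), and the defence genes CBP60G (-1.97 ± 0.18) and WRKY18 (-1.24 ± 0.09) fell. The flavonoid genes LDOX (1.48 ± 0.07) and DFR (1.42 ± 0.07) rose, MYB111 (-1.64 ± 0.09) and UGT78D2 (-1.25 ± 0.05) fell, and the cold gene ERD10 (1.25 ± 0.08) rose while ZAT10 (-1.56 ± 0.11) fell.

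Warmth changed 6570 of 19190 tested genes in Col at 1 h, 3013 higher and 3557 lower. The larger share turned without Col 21C replicate 2 (3356 higher and 2996 lower) and at an absolute log2 fold change of at least 1 (245 and 236). Of 27 tested heat shock protein and factor genes, 21 rose (21 rose and 1 fell adjusted over the list alone), with a median of 1.55, camera adjusted p = 1.88e-19 and adjusted p = 0.0103 with an estimated correlation. Of 18 tested circadian clock genes, 15 fell (17 fell adjusted over the list alone), with a median of -0.60, camera adjusted p = 1.27e-09 and adjusted p = 0.105 with an estimated correlation. Of 12 tested salicylic acid defence genes, 10 fell (1 rose and 10 fell adjusted over the list alone), with a median of -0.76, camera adjusted p = 4.04e-05 and adjusted p = 0.0268 with an estimated correlation. Of 14 tested ethylene signalling genes, 11 fell (11 fell adjusted over the list alone), with a median of -0.26, camera adjusted p = 0.00171 and adjusted p = 0.156 with an estimated correlation. Of 19 tested thermosensory and photomorphogenesis regulator genes, 3 rose and 12 fell (3 rose and 12 fell adjusted over the list alone), with a median of -0.27, camera adjusted p = 0.00222 and adjusted p = 0.156 with an estimated correlation. Of 17 tested brassinosteroid and gibberellin genes, 3 rose and 9 fell (4 rose and 10 fell adjusted over the list alone), with a median of -0.31, camera adjusted p = 0.00251 and adjusted p = 0.0882 with an estimated correlation. Of 8 tested flowering time genes, 4 fell (4 fell adjusted over the list alone), with a median of -0.24, camera adjusted p = 0.0364 and adjusted p = 0.512 with an estimated correlation. Only the heat shock and salicylic acid lists kept their calls with the estimated correlation. The other 10 lists tested had medians from -0.09 to 0.22 and camera adjusted p of 0.0933 or more. The called genes in them were 2 up and 1 down of 19 INO80, SWR1 and H2A.Z genes, 2 up of 23 elongation and H3K4 methylation genes, 4 up and 5 down of 27 thermomorphogenesis and shade growth genes, 6 up and 5 down of 19 auxin-responsive genes and 5 up and 4 down of 24 photosynthesis genes. Called as well were 8 up and 6 down of 16 flavonoid genes, 8 up and 5 down of 16 cold genes, 1 down of 12 DNA damage genes, 4 up and 2 down of 16 root markers and 2 up of 12 seed markers. HSP17 and LSU genes have near-identical copies, so values of single members are uncertain.

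The same comparison in ino80 asked whether the mutant responds to 1 h of warmth. EXPA16 rose by 3.45 ± 0.09, HSP17.8 by 3.41 ± 0.09, AT5G48570 by 3.34 ± 0.08 and AT5G51440 by 3.26 ± 0.10. HSP70-4 rose by 2.99 ± 0.06, from 182 ± 7.86 to 1453 ± 22.3 TPM, and HSFA2 by 2.82 ± 0.08. PIF4 rose by 0.75 ± 0.10 (adjusted p = 3.2e-05), from 15.7 ± 1.45 to 27.1 ± 0.327 TPM, and its response did not differ between genotypes by the test of the interaction (adjusted p = 0.94).

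ATSDI1 (-4.03 ± 0.12), LSU3 (-3.11 ± 0.21), SHM7 (-2.97 ± 0.08), APR1 (-2.92 ± 0.08) and GA2OX2 (-2.83 ± 0.11) were among the genes that fell most. GA3OX1 (1.87 ± 0.11), PIF5 (0.55 ± 0.06), BES1 (0.65 ± 0.06) and ERD10 (1.30 ± 0.08) rose, and BBX18 (-0.93 ± 0.05), HYH (-1.25 ± 0.06), HY5 (-1.04 ± 0.09), GI (-1.19 ± 0.06), PRR5 (-1.39 ± 0.12), CBP60G (-1.73 ± 0.18), SNC1 (-0.97 ± 0.07), PIN3 (-0.68 ± 0.06) and MYB111 (-1.80 ± 0.09) fell. HSP90.1 rose less than in Col (2.73 ± 0.08), with an interaction of -0.57 ± 0.11, adjusted p = 0.018. That adjusted p was 0.056 without Col 27C replicate 2, 0.0552 without Col 27C replicate 3 and 0.0507 without ino80 27C replicate 1. Of the 13 genes fixed by name, 5 rose and 1 fell, and the 7 others changed by -0.15 to 0.04. No gene among them passed the interaction test at 1 h, where their values ran from -0.33 to 0.33.

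In ino80, warmth changed 6141 genes at 1 h, 2917 higher and 3224 lower, or 253 and 160 at an absolute log2 fold change of at least 1. Of 27 tested heat shock protein and factor genes, 23 rose (24 rose adjusted over the list alone), with a median of 1.40, camera adjusted p = 3.68e-22 and adjusted p = 0.00666 with an estimated correlation. Of 18 tested circadian clock genes, 15 fell (1 rose and 17 fell adjusted over the list alone), with a median of -0.55, camera adjusted p = 2.54e-11 and adjusted p = 0.0722 with an estimated correlation. Of 12 tested salicylic acid defence genes, 8 fell (8 fell adjusted over the list alone), with a median of -0.43, camera adjusted p = 0.000191 and adjusted p = 0.0418 with an estimated correlation. Of 14 tested ethylene signalling genes, 9 fell (10 fell adjusted over the list alone), with a median of -0.30, camera adjusted p = 0.000848 and adjusted p = 0.136 with an estimated correlation. Of 19 tested thermosensory and photomorphogenesis regulator genes, 2 rose and 11 fell (4 rose and 12 fell adjusted over the list alone), with a median of -0.26, camera adjusted p = 0.00795 and adjusted p = 0.252 with an estimated correlation. Of 17 tested brassinosteroid and gibberellin genes, 2 rose and 10 fell (3 rose and 11 fell adjusted over the list alone), with a median of -0.21, camera adjusted p = 0.000848 and adjusted p = 0.0553 with an estimated correlation. Of 16 tested cold-responsive genes, 9 rose and 3 fell (9 rose and 4 fell adjusted over the list alone), with a median of 0.45, camera adjusted p = 0.00352 and adjusted p = 0.416 with an estimated correlation. Again the heat shock and salicylic acid lists alone kept their calls with the estimated correlation, and the other 10 lists had medians from -0.19 to 0.16. The genes called in each genotype overlapped. Of 3013 genes that rose in Col and 2917 in ino80, 1884 were the same (458 by chance), and 2316 of the falling genes were (597.6 by chance).

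Comparing the genotypes at 21 °C asked what the mutation changes without warmth. At the 1 h time point the lectin gene AT1G52000 (4.09 ± 0.14), AT3G03776 (3.60 ± 0.14) and the allene oxide cyclase AOC2 (2.96 ± 0.08) were higher in ino80. AT2G40570 (-2.95 ± 0.13), AT4G19950 (-2.80 ± 0.14) and the chloroplast NDH subunit gene PnsB1 (-2.17 ± 0.06) were lower. The floral repressor FLC was 13.6 ± 0.958 TPM in ino80 and 5.54 ± 0.27 in Col (1.16 ± 0.08, adjusted p = 2.5e-08), and WRKY40 was 1.07 ± 0.09 and 9.88 ± 2.01 (-2.38 ± 0.14, adjusted p = 6.4e-09). The cruciferin genes CRA1 (2.38 ± 0.11) and CRU3 (2.68 ± 0.34) were higher.

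Growth regulators changed both ways, with PIF7 (-1.28 ± 0.08) and the auxin gene DFL1 (-0.99 ± 0.10) lower and PIL1 (1.10 ± 0.12), PIF3 (0.69 ± 0.08), BAS1 (0.92 ± 0.09) and GID1A (0.73 ± 0.08) higher. The flowering genes MAF5 (1.18 ± 0.14) and MAF2 (0.53 ± 0.08) were higher and SOC1 (-0.79 ± 0.12) lower. The flavonoid genes DFR (1.38 ± 0.07), TT19 (1.13 ± 0.07), LDOX (1.07 ± 0.07) and PAP1 (0.84 ± 0.06) and the cold genes COR15B (1.11 ± 0.12) and RD29A (0.61 ± 0.08) were higher. MLP328 (-2.14 ± 0.09), ARR15 (-2.19 ± 0.14) and ANNAT7 (-2.02 ± 0.17) were lower, as were HSP17.8 (-1.15 ± 0.09), HSP70-4 (-0.79 ± 0.06), HSFA2 (-0.85 ± 0.08) and WRKY33 (-0.97 ± 0.11). Among elongation and H3K4 methylation genes ATX4 (1.06 ± 0.11) and SSRP1 (0.34 ± 0.05) were higher, among DNA damage genes GMI1 (1.50 ± 0.13) higher and TSO2 (-0.74 ± 0.08) lower, and among ethylene genes ERS2 (1.17 ± 0.10) higher. The root markers PYK10 (0.34 ± 0.04) and IRT1 (0.86 ± 0.12) and the floral marker PI (1.09 ± 0.13) were higher too.

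Between the genotypes 6880 genes differed at 21 °C and 1 h, 2950 higher and 3930 lower in ino80. The larger share turned with the TPM rescaled by the median of ratios (3678 higher and 3546 lower), with quantile normalization (3669 and 3608) and without Col 21C replicate 2 (3330 and 3282). Of 12 tested seed maturation marker genes, 9 were higher and 1 lower (10 were higher and 1 lower adjusted over the list alone), with a median of 1.23, camera adjusted p = 0.000106 and adjusted p = 0.492 with an estimated correlation. Of 16 tested anthocyanin and flavonoid genes, 8 were higher and 2 lower (8 were higher and 3 lower adjusted over the list alone), with a median of 0.15, camera adjusted p = 0.000106 and adjusted p = 0.37 with an estimated correlation. Of 24 tested photosynthesis and chlorophyll genes, 11 were higher and 1 lower (11 were higher and 1 lower adjusted over the list alone), with a median of 0.12, camera adjusted p = 0.00213 and adjusted p = 0.501 with an estimated correlation. Of 16 tested cold-responsive genes, 8 were higher and 2 lower (8 were higher and 2 lower adjusted over the list alone), with a median of 0.26, camera adjusted p = 0.0198 and adjusted p = 0.501 with an estimated correlation. Of 27 tested heat shock protein and factor genes, 3 were higher and 14 lower (4 were higher and 14 lower adjusted over the list alone), with a median of -0.25, camera adjusted p = 0.0198 and adjusted p = 0.501 with an estimated correlation. Of 8 tested flowering time genes, 4 were higher and 1 lower (4 were higher and 1 lower adjusted over the list alone), with a median of 0.36, camera adjusted p = 0.0378 and adjusted p = 0.501 with an estimated correlation. With the estimated correlation no camera call held here, where fry called 9 of 17 lists. The other 11 lists had medians from -0.10 to 0.19, and in them the called genes were 2 up and 4 down of 19 INO80, SWR1 and H2A.Z genes, 5 up and 3 down of 23 elongation and H3K4 methylation genes, 6 up and 2 down of 27 thermomorphogenesis and shade growth genes, 6 up and 1 down of 19 thermosensory regulators, 5 up and 2 down of 19 auxin-responsive genes and 7 up and 4 down of 17 brassinosteroid and gibberellin genes. Called as well were 4 up and 1 down of 18 clock genes, 2 up and 3 down of 12 salicylic acid genes, 3 up and 1 down of 12 DNA damage genes, 3 up and 2 down of 14 ethylene genes and 3 up and 1 down of 16 root markers. Early touch and wound genes, a list chosen after the data were seen, were lower in ino80 at 21 °C in 11 of 13 members. Camera gave adjusted p = 2.68e-06, or 0.114 with an estimated correlation.

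At 27 °C and 1 h the same comparison asked what differs under warmth. AT1G52000 (3.56 ± 0.14), AT3G03776 (3.41 ± 0.14), AOC2 (3.0 ± 0.08), GH9B15 (2.58 ± 0.12), CRU3 (2.86 ± 0.34) and CRA1 (2.70 ± 0.11) were higher in ino80. AT2G40570 (-3.10 ± 0.13), AT3G62460 (-2.75 ± 0.12), CRK12 (-2.72 ± 0.12), PnsB1 (-2.15 ± 0.06) and ANNAT7 (-2.06 ± 0.17) were lower. FLC (1.43 ± 0.08, adjusted p = 3.3e-09), MAF5 (1.35 ± 0.14) and MAF2 (0.77 ± 0.08) were higher. The heat shock genes HSP17.6II (-1.68 ± 0.12), HSP17.6B (-1.60 ± 0.14), HSP101 (-0.65 ± 0.06) and HSP70-4 (-0.67 ± 0.06) were lower. PIF7 (-1.21 ± 0.08, adjusted p = 3.2e-08) was lower, and PIL1 (0.78 ± 0.12), BR6OX2 (0.79 ± 0.06), WRKY18 (1.05 ± 0.09), TT8 (1.29 ± 0.11), ERD10 (0.68 ± 0.08), ERS2 (0.99 ± 0.10), ATX4 (0.90 ± 0.11) and GMI1 (1.21 ± 0.13) were higher. TSO2 (-0.91 ± 0.08), IAA30 (-0.81 ± 0.15) and the root markers PRP3 (-0.83 ± 0.13) and COBL9 (-0.54 ± 0.10) were lower, and the floral marker PI (0.64 ± 0.13) was higher.

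At 27 °C and 1 h 7183 genes differed, 3277 higher and 3906 lower in ino80, or 3973 and 3755 with the TPM rescaled by the median of ratios. Of 16 tested cold-responsive genes, 11 were higher (13 were higher adjusted over the list alone), with a median of 0.47, camera adjusted p = 0.000116 and adjusted p = 0.367 with an estimated correlation. Of 12 tested seed maturation marker genes, 10 were higher and 1 lower (10 were higher and 1 lower adjusted over the list alone), with a median of 1.31, camera adjusted p = 0.000229 and adjusted p = 0.367 with an estimated correlation. Of 8 tested flowering time genes, 6 were higher and 1 lower (6 were higher and 1 lower adjusted over the list alone), with a median of 0.43, camera adjusted p = 0.00264 and adjusted p = 0.367 with an estimated correlation. Of 24 tested photosynthesis and chlorophyll genes, 12 were higher and 2 lower (14 were higher and 2 lower adjusted over the list alone), with a median of 0.15, camera adjusted p = 0.00848 and adjusted p = 0.613 with an estimated correlation. Of 27 tested heat shock protein and factor genes, 3 were higher and 12 lower (3 were higher and 12 lower adjusted over the list alone), with a median of -0.22, camera adjusted p = 0.00973 and adjusted p = 0.407 with an estimated correlation. Of 17 tested brassinosteroid and gibberellin genes, 6 were higher and 1 lower (6 were higher and 1 lower adjusted over the list alone), with a median of 0.15, camera adjusted p = 0.027 and adjusted p = 0.367 with an estimated correlation. None of these calls held with the estimated correlation, and fry called 9 of the 17 lists. The other 11 lists had medians from -0.18 to 0.09. In all, 2087 genes were higher in ino80 at both temperatures (503.8 by chance) and 2622 lower (799.9 by chance), while 14 and 36 were called in opposite directions. With the TPM rescaled by the median of ratios 2611 and 2415 were higher and lower at both.

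Whether the genotypes respond differently to 1 h of warmth was tested by the genotype by temperature interaction, the change with warmth in ino80 less that in Col. Positive values were found for WRKY40 (1.55 ± 0.20, adjusted p = 0.00071), CAF1a (1.43 ± 0.20), DIC2 (1.38 ± 0.15) and ZAT10 (1.27 ± 0.16). WRKY40 fell from 9.88 ± 2.01 to 2.5 ± 0.476 TPM in Col and was 1.07 ± 0.09 and 0.97 ± 0.187 in ino80. The cytokinin response gene ARR15 (1.21 ± 0.19) and WRKY33 (1.03 ± 0.15) were positive too. AT1G12030 (-2.47 ± 0.19, adjusted p = 2e-05), the low-sulfur genes LSU1 (-1.52 ± 0.21) and ATSDI1 (-1.42 ± 0.17), TRM13 (-1.29 ± 0.17) and the nitrate reductase NIA1 (-1.27 ± 0.11, adjusted p = 2.1e-05) had negative values, as had EXO (-0.99 ± 0.12), AT5G12110 (-0.99 ± 0.11) and GIS (-0.97 ± 0.11). Among growth genes DFL1 (0.79 ± 0.14, adjusted p = 0.0079) was positive, and PIN3 (-0.52 ± 0.09, adjusted p = 0.008) and BAS1 (-0.72 ± 0.12, adjusted p = 0.0057) were negative. The clock output gene CDF1 (-0.51 ± 0.09, adjusted p = 0.0085) and the flavonoid genes PAL1 (-0.37 ± 0.06) and 4CL3 (-0.36 ± 0.07) were negative as well.

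The interaction called 361 genes at 1 h, 209 positive and 152 negative. At an absolute log2 fold change of at least 1 these were 48 and 7. The response was larger in Col for 196 of them and larger in ino80 for 165, and the estimates had opposite signs for 128, of which 38 were called in both genotypes. Fewer genes were called without some single libraries, with 199 without Col 21C replicate 3, 186 without Col 27C replicate 2, 214 without Col 27C replicate 3, 196 without ino80 27C replicate 1 and 215 without ino80 27C replicate 2. Without Col 21C replicate 2 the split was 214 positive and 225 negative. Anthocyanin and flavonoid genes (median -0.14, camera adjusted p = 5.93e-06) and root markers (median -0.12, adjusted p = 0.0155) had negative values, and flowering time genes (median 0.20, adjusted p = 0.0421) positive ones. With an estimated correlation these gave adjusted p = 0.211, 0.353 and 0.635. Of the 3 lists 5 of 16 flavonoid genes and 1 of 16 root markers passed, with 6 and 1 adjusted over the list alone. The heat shock list did not pass (median 0.06, mean -0.01, adjusted p = 0.832).

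Chloroplast-encoded transcripts summed to 1274 ± 262 TPM (SD, n = 3) in Col at 21 °C and 890 ± 111 at 27 °C, and to 1607 ± 259 and 2363 ± 256 in ino80. On the log2 scale the warmth changes of the genotypes differed by 1.07 ± 0.25, and mitochondrion-encoded transcripts by 0.41 ± 0.17. ATCG00350 (2.99 ± 0.35, adjusted p = 0.00044) and ATCG00270 (2.24 ± 0.33, adjusted p = 0.0022) led the positive interaction genes. At 12 h the chloroplast difference was 0.10 ± 0.09.

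**Figure D2:**
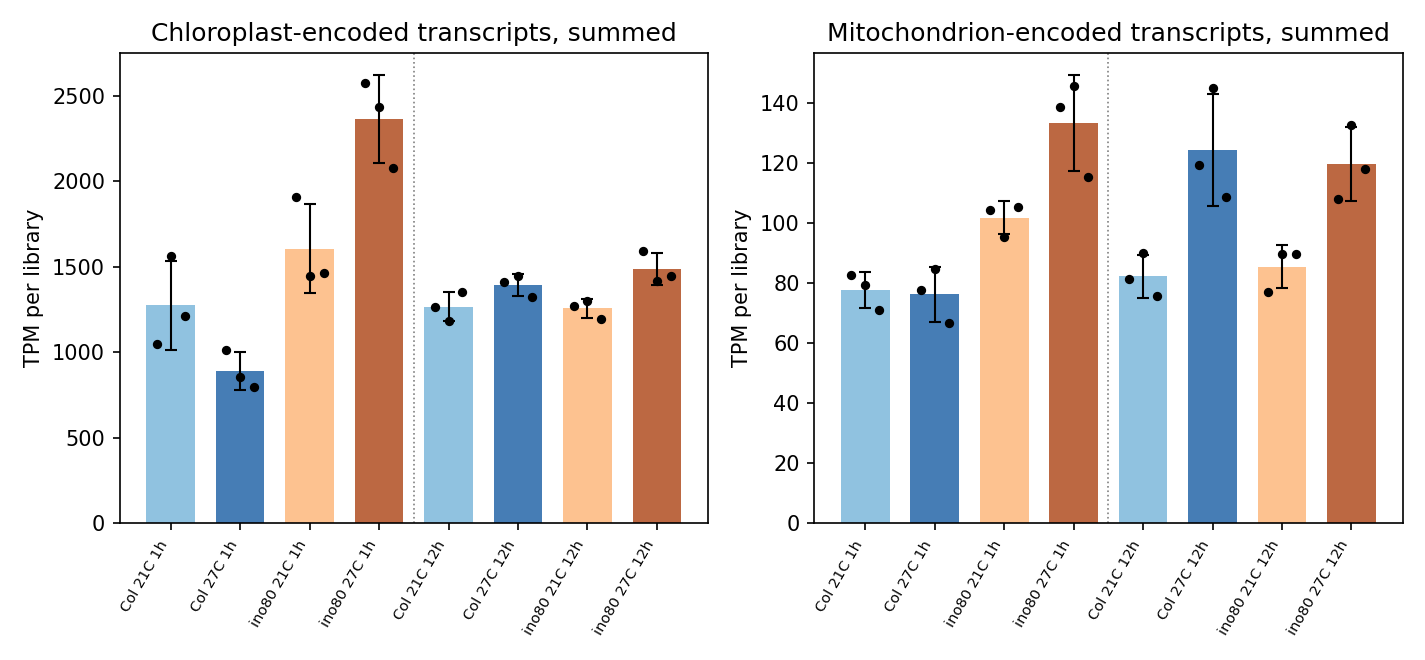
Summed TPM of chloroplast-encoded and of mitochondrion-encoded transcripts in every library (points), with the group mean (bars) and SD (lines, n = 3), both axes from 0. At 1 h the chloroplast sum fell with warmth in Col and rose in ino80, to 2363 TPM.

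The share of the Col response kept in ino80 was taken as the median change in ino80 over that in a left-out Col replicate, for genes chosen in the other Col replicates. It averaged 0.891 ± 0.131 (SD over the 3 left-out replicates) for rising genes and 0.827 ± 0.134 for falling genes at 1 h. At 12 h it averaged 0.973 ± 0.115 and 0.878 ± 0.096. Each of the 4 averages lay within 2 SD of 1, so they were not separated from 1 by the spread between replicates. With the TPM rescaled by the median of ratios the mean over both directions was 0.835 ± 0.021 at 1 h and 0.903 ± 0.068 at 12 h. A ratio from the covariance of the responses over all tested genes was 0.84 at 1 h and 0.907 at 12 h.

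**Figure D3:**
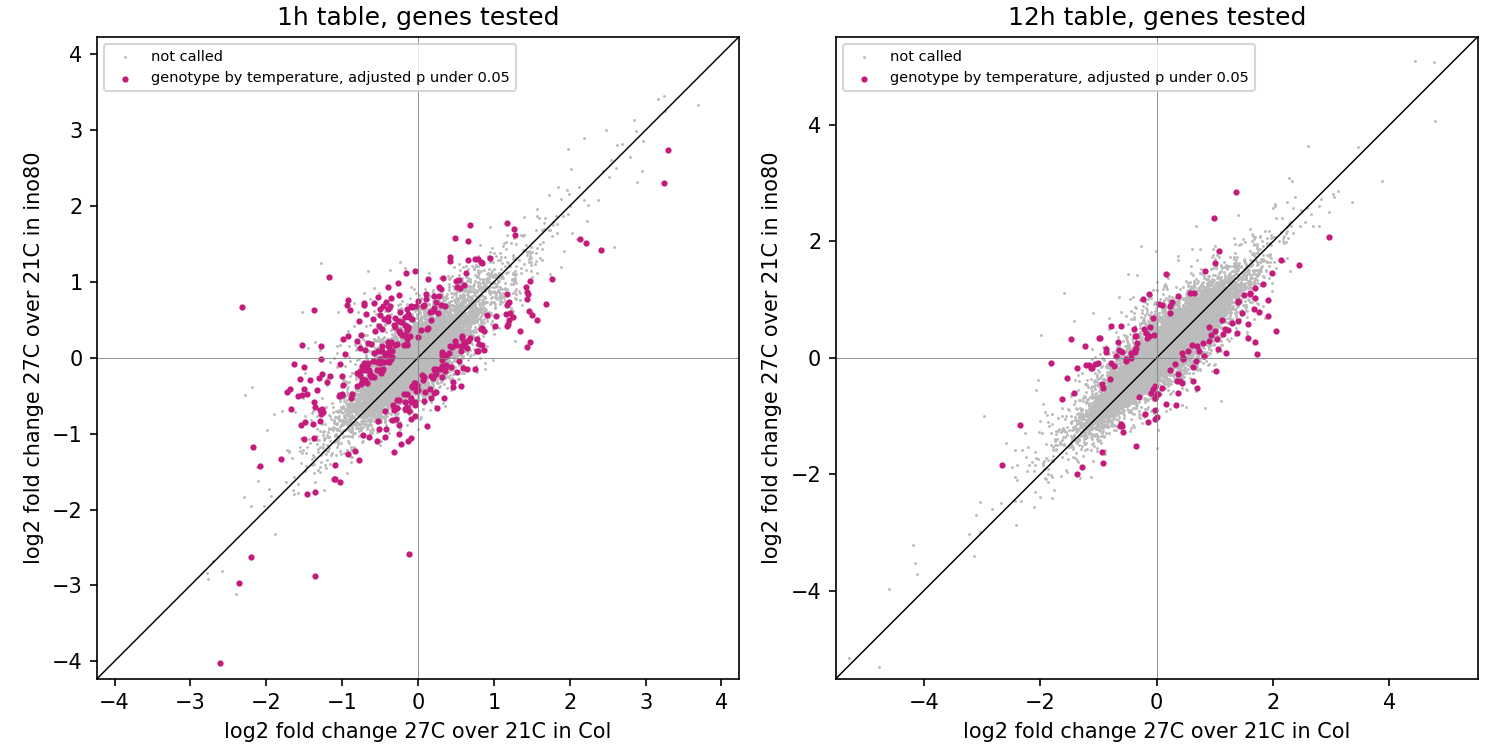
Log2 fold change with warmth in ino80 (vertical) against Col (horizontal) for each tested gene at 1 h and 12 h, with the line of equal change and the genes called by the interaction coloured. The interaction called 361 genes at 1 h and 147 at 12 h.

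After 12 h at 27 °C the comparison in Col asked which transcripts change with lasting warmth. The time of day may differ from that of the 1 h samples. PIF4 rose by 2.79 ± 0.14, adjusted p = 1.2e-09, from 2.37 ± 0.524 to 22.3 ± 3.1 TPM (SD, n = 3). SEN1 (4.78 ± 0.15), the leucine-rich repeat gene AT2G15880 (4.76 ± 0.21) and the asparagine synthetase ASN1 (4.44 ± 0.19) rose most. COR15A (-5.28 ± 0.26), CAB2 (-4.77 ± 0.18) and the flavonoid genes TT19 (-4.60 ± 0.34), LDOX (-4.19 ± 0.27) and DFR (-4.13 ± 0.29) were among those that fell most. SAUR19 (2.04 ± 0.21), IAA29 (1.50 ± 0.19) and HSP70-4 (1.67 ± 0.15) also rose. The median change of all tested genes was 0.128 in Col and 0.150 in ino80 with the TPM as deposited, and changes at 12 h are to be read relative to it.

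FLP1 (3.87 ± 0.24), RTFL21 (3.45 ± 0.17), AT4G27450 (3.12 ± 0.11) and the homogentisate dioxygenase HGO (3.04 ± 0.12) rose, and COR15B (-4.16 ± 0.22), AT5MAT (-3.22 ± 0.21) and UF3GT (-3.14 ± 0.27) fell. The growth genes PIF5 (1.58 ± 0.10), PAR1 (1.54 ± 0.14), EXPA8 (1.01 ± 0.09), GH3.5 (1.13 ± 0.09) and CPD (1.43 ± 0.06) rose, and GA3OX1 (-2.09 ± 0.16) fell. Of the 16 genes fixed by name 11 rose and 2 fell, HTA8 (-0.49 ± 0.10) and HTA11 (-0.45 ± 0.07), while HTA9 rose (0.89 ± 0.06). YUC8, IAA19 and FLC did not pass, at 0.21 to 0.33, and FT was not in the 12 h table. The clock and light genes LUX (2.96 ± 0.11), TOC1 (1.46 ± 0.09), COR27 (1.74 ± 0.08) and RVE4 (1.03 ± 0.06) rose, and HMR (-1.48 ± 0.09) and HYH (-2.13 ± 0.15) fell. MBF1C (1.72 ± 0.09), GOLS1 (1.77 ± 0.14), HSP90.1 (1.89 ± 0.15), SVP (1.20 ± 0.07), EBF2 (0.82 ± 0.07), EIN3 (0.73 ± 0.07), VIP5 (0.92 ± 0.07) and CASP2 (0.99 ± 0.16) rose. CHS (-3.04 ± 0.21), PR5 (-2.01 ± 0.19), TSO2 (-1.08 ± 0.08), CAB3 (-1.81 ± 0.10) and IRT1 (-1.85 ± 0.34) fell, and the seed markers OLEO2 (1.56 ± 0.14) and EM6 (1.20 ± 0.19) rose. Of the 19 INO80, SWR1 and H2A.Z genes 13 passed, NRP1 (-0.81 ± 0.09) and NRP2 (-0.89 ± 0.09) among those that fell, and the others changed by -0.39 to 0.18.

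Warmth changed 11475 of 19578 tested genes in Col at 12 h, 7201 higher and 4274 lower. With the TPM rescaled by the median of ratios the calls split into 5546 higher and 5598 lower. Of 16 tested anthocyanin and flavonoid genes, 15 fell (15 fell adjusted over the list alone), with a median of -1.92, camera adjusted p = 2.7e-10 and adjusted p = 0.156 with an estimated correlation. Of 18 tested circadian clock genes, 17 rose (17 rose adjusted over the list alone), with a median of 0.63, camera adjusted p = 1.63e-05 and adjusted p = 0.156 with an estimated correlation. Of 29 tested thermomorphogenesis and shade growth genes, 21 rose and 1 fell (21 rose and 1 fell adjusted over the list alone), with a median of 1.01, camera adjusted p = 0.00193 and adjusted p = 0.156 with an estimated correlation. Of 15 tested ethylene signalling genes, 11 rose and 1 fell (11 rose and 1 fell adjusted over the list alone), with a median of 0.51, camera adjusted p = 0.0202 and adjusted p = 0.47 with an estimated correlation. None kept its call with the estimated correlation, and fry called 13 of the 17 lists. In the 13 others the called genes were 6 up and 7 down of 19 INO80, SWR1 and H2A.Z genes, 9 up and 2 down of 23 elongation and H3K4 methylation genes, 12 up and 4 down of 19 thermosensory regulators, 13 up of 21 auxin-responsive genes, 9 up and 1 down of 14 brassinosteroid and gibberellin genes, 13 up and 3 down of 24 heat shock genes and 2 up and 2 down of 9 flowering time genes. Called as well were 10 up and 11 down of 24 photosynthesis genes, 5 up and 3 down of 14 cold genes, 2 up and 4 down of 15 salicylic acid genes, 3 down of 11 DNA damage genes, 5 up and 1 down of 14 root markers and 5 up of 12 seed markers. The LHCB1 genes CAB2 and CAB3, and SAUR19 to SAUR24, have near-identical copies, so values of single members are uncertain.

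In ino80 the 12 h comparison asked whether the mutant changes the same transcripts. PIF4 rose by 2.27 ± 0.14, adjusted p = 9.6e-09, from 2.05 ± 0.26 to 13.8 ± 1.99 TPM. Its level at 27 °C differed from that of Col by -0.66 ± 0.14 (adjusted p = 0.00318), a value chosen after it was seen, and the interaction was -0.52 ± 0.20, adjusted p = 0.32. ASN1 (5.11 ± 0.19), AT2G15880 (5.08 ± 0.21), SEN1 (4.07 ± 0.15) and the threonine aldolase THA1 (3.65 ± 0.20) rose most. CAB2 (-5.31 ± 0.18), COR15A (-5.17 ± 0.26), TT19 (-3.98 ± 0.34) and DFR (-3.71 ± 0.29) had the largest falls.

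Also rising were SAUR19 (2.07 ± 0.21), IAA29 (1.25 ± 0.19), EXPA8 (1.63 ± 0.09), PIF5 (1.44 ± 0.10), PAR1 (1.62 ± 0.14), GH3.5 (1.27 ± 0.09), CPD (1.24 ± 0.06), HSP70-4 (2.04 ± 0.15), HSP90.1 (2.05 ± 0.15), MBF1C (1.93 ± 0.09), LUX (2.51 ± 0.11), TOC1 (1.35 ± 0.09), SVP (1.31 ± 0.07), FLC (0.48 ± 0.11), VIP5 (0.95 ± 0.07) and BCAT-2 (3.04 ± 0.18). Falling genes were COR15B (-3.52 ± 0.22), LDOX (-3.21 ± 0.27), UF3GT (-3.40 ± 0.27), AT5MAT (-3.03 ± 0.21), CHS (-3.00 ± 0.21), MYB111 (-2.27 ± 0.14), GA3OX1 (-1.84 ± 0.16), RBCS1B (-1.58 ± 0.08), HMR (-1.35 ± 0.09), PR5 (-1.09 ± 0.19) and TSO2 (-1.11 ± 0.08). Of the 16 genes fixed by name 13 rose and 2 fell, HTA8 (-0.40 ± 0.10) and HTA11 (-0.36 ± 0.07), and IAA19 did not pass (0.26 ± 0.18) except without ino80 27C replicate 1 (adjusted p = 0.027). The interaction test called none of them at 12 h, with values from -0.59 to 0.52. Of the 19 INO80, SWR1 and H2A.Z genes 14 passed, HTA9 (0.86 ± 0.06) and NRP2 (-0.78 ± 0.09) among them, and the others changed by -0.28 to 0.25.

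In ino80 11241 genes changed with warmth at 12 h, 7458 higher and 3783 lower, or 5208 and 5444 with the TPM rescaled by the median of ratios. Of 16 tested anthocyanin and flavonoid genes, 14 fell (14 fell adjusted over the list alone), with a median of -2.20, camera adjusted p = 6.87e-12 and adjusted p = 0.17 with an estimated correlation. Of 18 tested circadian clock genes, 16 rose (16 rose adjusted over the list alone), with a median of 0.80, camera adjusted p = 1.52e-05 and adjusted p = 0.17 with an estimated correlation. Of 24 tested heat shock protein and factor genes, 18 rose and 2 fell (18 rose and 2 fell adjusted over the list alone), with a median of 0.89, camera adjusted p = 0.00475 and adjusted p = 0.222 with an estimated correlation. Of 29 tested thermomorphogenesis and shade growth genes, 20 rose and 4 fell (20 rose and 4 fell adjusted over the list alone), with a median of 0.91, camera adjusted p = 0.0147 and adjusted p = 0.247 with an estimated correlation. Of 21 tested auxin-responsive genes, 13 rose and 1 fell (13 rose and 1 fell adjusted over the list alone), with a median of 0.46, camera adjusted p = 0.0184 and adjusted p = 0.265 with an estimated correlation. Of 14 tested brassinosteroid and gibberellin genes, 10 rose and 2 fell (10 rose and 2 fell adjusted over the list alone), with a median of 0.37, camera adjusted p = 0.0416 and adjusted p = 0.199 with an estimated correlation. Of 15 tested ethylene signalling genes, 11 rose and 1 fell (11 rose and 1 fell adjusted over the list alone), with a median of 0.55, camera adjusted p = 0.0409 and adjusted p = 0.539 with an estimated correlation. No call held with the estimated correlation, and fry called 12 of the 17 lists. The 10 others had medians from -0.13 to 0.39. In all, 6104 genes rose in both genotypes (2743.1 by chance) and 3259 fell in both (825.9 by chance), or 4318 and 4590 with the TPM rescaled by the median of ratios.

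**Figure D4:**
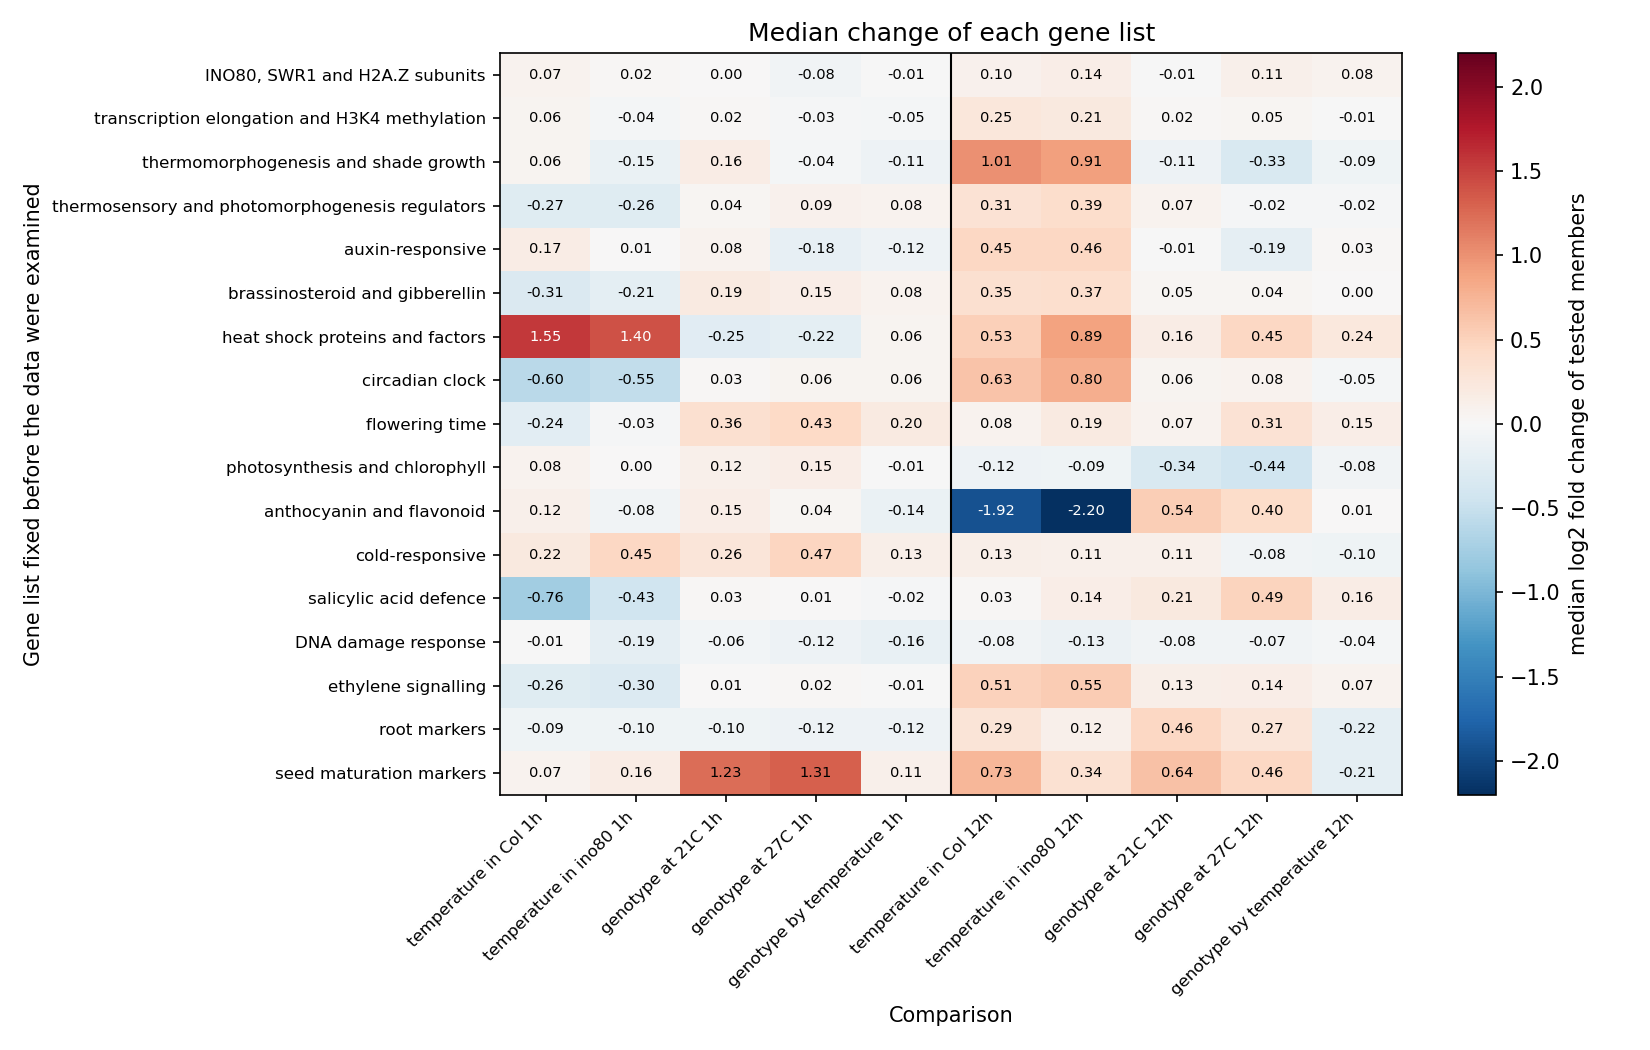
Median log2 fold change of the tested members of 17 gene lists (vertical) in the 10 comparisons (horizontal), with the TPM as deposited, coloured from lower (blue) to higher (red). The flavonoid list had medians of -1.92 in Col and -2.20 in ino80 after 12 h of warmth.

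The genotypes were compared again at 21 °C after 12 h, to ask which differences hold at the later time point. AT3G03776 (3.37 ± 0.20), AT5G42530 (3.17 ± 0.25), EARLI1 (2.87 ± 0.19), the thionin THI2.2 (2.42 ± 0.13) and the light-harvesting gene LHCB4.3 (2.38 ± 0.16) were higher in ino80. AT2G18630 (-3.40 ± 0.13), AT2G40570 (-3.17 ± 0.13), PnsB1 (-2.52 ± 0.07), SEP4 (-2.52 ± 0.16), the histone deacetylase HDA2 (-2.20 ± 0.14) and ESM1 (-2.07 ± 0.08) were lower. FLC (1.11 ± 0.11, adjusted p = 3.7e-06) and MAF5 (1.18 ± 0.16) were higher and SOC1 (-1.13 ± 0.20) lower. Of other light-harvesting and chlorophyll genes, PORB (-0.94 ± 0.06), LHCB4.2 (-1.03 ± 0.07), LHCB2.2 (-1.34 ± 0.10) and LHCB2.1 (-1.29 ± 0.11) were lower. PIF7 (-1.40 ± 0.14), SAUR24 (-1.06 ± 0.23) and SAUR21 (-0.96 ± 0.21) were lower, and XTH15 (1.10 ± 0.20), TAA1 (0.56 ± 0.07), BRU6 (1.46 ± 0.17) and ELF4 (0.57 ± 0.06) higher. HSFA7A (1.07 ± 0.10), HSP90.1 (0.76 ± 0.15), DFR (1.64 ± 0.29), WRKY18 (0.91 ± 0.14), GMI1 (1.54 ± 0.14), ATX4 (0.86 ± 0.12) and ATX5 (0.76 ± 0.14) were higher too. The seed marker CRA1 (2.21 ± 0.36), the root marker PYK10 (0.91 ± 0.10) and CASP2 (0.85 ± 0.16) were higher, and HSP17.6B (-1.41 ± 0.19) lower. The floral marker PI was higher (0.79 ± 0.21, adjusted p = 0.013), and its adjusted p was 0.0561 without Col 21C replicate 1 and 0.06 without ino80 21C replicate 2.

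At 21 °C and 12 h 5639 genes differed, 3273 higher and 2366 lower in ino80, or 2813 and 3036 with the TPM rescaled by the median of ratios. Of 24 tested photosynthesis and chlorophyll genes, 1 were higher and 15 lower (2 were higher and 16 lower adjusted over the list alone), with a median of -0.34, camera adjusted p = 2.53e-08 and adjusted p = 0.815 with an estimated correlation. Of 16 tested anthocyanin and flavonoid genes, 9 were higher (12 were higher adjusted over the list alone), with a median of 0.54, camera adjusted p = 0.00174 and adjusted p = 0.853 with an estimated correlation. Of 15 tested ethylene signalling genes, 6 were higher (6 were higher adjusted over the list alone), with a median of 0.13, camera adjusted p = 0.0496 and adjusted p = 0.853 with an estimated correlation. Of 14 tested root marker genes, 6 were higher and 1 lower (6 were higher and 1 lower adjusted over the list alone), with a median of 0.46, camera adjusted p = 0.0496 and adjusted p = 0.853 with an estimated correlation. Of 12 tested seed maturation marker genes, 5 were higher and 1 lower (6 were higher and 1 lower adjusted over the list alone), with a median of 0.64, camera adjusted p = 0.0496 and adjusted p = 0.853 with an estimated correlation. The estimated correlation left none of these calls, and fry called 5 of the 17 lists. The 12 others had medians from -0.11 to 0.21, and the called genes in them were 4 down of 19 INO80, SWR1 and H2A.Z genes, 6 up and 1 down of 23 elongation and H3K4 methylation genes, 5 up and 6 down of 29 thermomorphogenesis and shade growth genes, 5 up and 2 down of 19 thermosensory regulators, 4 up and 6 down of 21 auxin-responsive genes and 3 up and 2 down of 14 brassinosteroid and gibberellin genes. Called as well were 7 up and 3 down of 24 heat shock genes, 7 up and 1 down of 18 clock genes, 2 up and 2 down of 9 flowering time genes, 2 up and 1 down of 14 cold genes, 3 up of 15 salicylic acid genes and 2 up and 2 down of 11 DNA damage genes.

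At 27 °C and 12 h the comparison asked how the genotypes differ in lasting warmth. AT2G25510 (3.58 ± 0.23), AT4G29200 (3.53 ± 0.15), CYP82C2 (3.16 ± 0.54), LCR67 (2.85 ± 0.56) and Prx37 (2.57 ± 0.31) were higher in ino80. AT2G18630 (-3.43 ± 0.13), AT2G40570 (-3.41 ± 0.13), PnsB1 (-3.40 ± 0.07), HDA2 (-2.92 ± 0.14), SEP4 (-2.81 ± 0.16), ESM1 (-2.58 ± 0.08) and EMB3114 (-2.39 ± 0.08) were lower. FLC (1.38 ± 0.11, adjusted p = 4.7e-07) and MAF5 (1.30 ± 0.16) were higher. Of the growth genes PIF7 (-1.49 ± 0.14) and the auxin synthesis gene YUC9 (-1.23 ± 0.19) were lower, and XTH15 (1.40 ± 0.20), EXPA8 (0.51 ± 0.09), GH3.3 (1.57 ± 0.21), BRU6 (1.33 ± 0.17) and GA3OX1 (0.95 ± 0.16) higher. The light-harvesting genes LHCB6 (-1.0 ± 0.09), CAB3 (-1.18 ± 0.10), LHCB4.2 (-0.63 ± 0.07) and LHCB2.2 (-0.89 ± 0.10) were lower, and LHCB4.3 was higher (1.98), a value chosen after it was seen. The flavonoid genes DFR (2.06 ± 0.29), LDOX (1.99 ± 0.27) and TT19 (1.99 ± 0.34) and the defence genes WRKY18 (1.27 ± 0.14), WRKY70 (1.14 ± 0.20) and SARD1 (1.09 ± 0.22) were higher, as were HSFA7A (0.73 ± 0.10), HSP90.1 (0.93 ± 0.15), RVE1 (0.91 ± 0.10), ELF4 (0.62 ± 0.06), DET1 (0.81 ± 0.09), GMI1 (1.58 ± 0.14) and ATX4 (1.18 ± 0.12). The seed marker CRA1 (2.03 ± 0.36), the root markers PYK10 (0.82 ± 0.10) and RHD6 (0.78 ± 0.20) and the floral marker PI (1.24 ± 0.21) were higher. CRA1 was 4.6 ± 3.45 TPM in Col and 19.9 ± 5.2 in ino80.

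At 27 °C and 12 h 5916 genes differed, 3660 higher and 2256 lower in ino80, or 2703 and 3239 with the TPM rescaled by the median of ratios. Of 24 tested photosynthesis and chlorophyll genes, 17 were lower (18 were lower adjusted over the list alone), with a median of -0.44, camera adjusted p = 9.03e-12 and adjusted p = 0.403 with an estimated correlation. Of 24 tested heat shock protein and factor genes, 10 were higher (12 were higher adjusted over the list alone), with a median of 0.45, camera adjusted p = 0.0154 and adjusted p = 0.466 with an estimated correlation. Of 15 tested salicylic acid defence genes, 7 were higher (7 were higher adjusted over the list alone), with a median of 0.49, camera adjusted p = 0.0163 and adjusted p = 0.466 with an estimated correlation. Of 29 tested thermomorphogenesis and shade growth genes, 4 were higher and 10 lower (6 were higher and 10 lower adjusted over the list alone), with a median of -0.33, camera adjusted p = 0.0467 and adjusted p = 0.466 with an estimated correlation. None of the 4 calls held with the estimated correlation, and fry called 8 lists. The 13 others had medians from -0.19 to 0.46. At both temperatures 2189 genes were higher in ino80 (611.9 by chance) and 1472 lower (272.6 by chance), or 1693 and 2024 with the TPM rescaled by the median of ratios.

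The interaction at 12 h tested whether the genotypes respond differently to lasting warmth. The sulfate assimilation genes APR1 (1.79 ± 0.26, adjusted p = 0.009) and APR2 (1.04 ± 0.12, adjusted p = 0.0036) and the jasmonate synthesis genes LOX2 (1.74 ± 0.23, adjusted p = 0.0058) and AOC1 (1.33 ± 0.23, adjusted p = 0.018) had positive values. The defensin-like gene AT3G59930 (1.48 ± 0.23) was positive too. AT5G47590 (-1.65 ± 0.25, adjusted p = 0.0094), AT1G47980 (-1.58 ± 0.21, adjusted p = 0.0058), PELPK2 (-1.16 ± 0.19, adjusted p = 0.014), EMB3114 (-1.03 ± 0.12, adjusted p = 0.0036) and NIA1 (-1.21 ± 0.21, adjusted p = 0.019) were negative. The adjusted p of AT5G47590 was 0.271 with a pseudocount of 0.1. NIA1 was negative at 1 h as well, and its adjusted p at 12 h was 0.0708 with robust moderation, 0.0551 without Col 21C replicate 2 and 0.051 without ino80 21C replicate 1. PORB (0.48 ± 0.08, adjusted p = 0.017) was positive among photosynthesis genes, with adjusted p = 0.0506 without Col 21C replicate 3. Of the 16 genes with the largest values, 10 to 14 stayed called without each of the 12 libraries. AOC1 and AOC2 are near-identical copies, so their values are uncertain.

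At 12 h 147 genes were called, 64 positive and 83 negative. The larger share turned at an absolute log2 fold change of at least 1 (18 positive and 13 negative). It also turned without Col 21C replicate 1 (35 and 34) or 2 (37 and 34), Col 27C replicate 2 (54 and 49) or ino80 21C replicate 2 (45 and 35). Of the 147 genes the response was larger in Col for 92 and in ino80 for 55, and the estimates had opposite signs for 48, of which 17 were called in both genotypes. With the replicate block 93 genes were called, 47 positive and 46 negative, and 11 of the 16 leading genes. The count also fell without single libraries, to 69, 71 and 54 without Col 21C replicates 1, 2 and 3, to 75 and 80 without ino80 21C replicates 1 and 2, and to 80 and 83 without ino80 27C replicates 1 and 2. Heat shock genes (median 0.24, camera adjusted p = 0.0375) had positive and seed maturation markers (median -0.21, adjusted p = 0.0375) negative values, both with adjusted p = 0.771 with an estimated correlation. The 15 other lists had medians from -0.22 to 0.16.

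Calls at 1 h and 12 h were compared by Fisher's exact test (two-sided) over the 18827 genes tested at both times. In Col 1113 genes rose at both times (1098.5 by chance, odds ratio 1.03, exact p = 0.548) and 804 fell (778.3 by chance, odds ratio 1.05, exact p = 0.251). At an absolute log2 fold change of at least 1 these were 33 (11.7 by chance, odds ratio 3.21, exact p = 6.91e-08) and 25 (6.2 by chance, odds ratio 4.56, exact p = 3.88e-09). Of 4123 genes called in Col at both times, 2206 changed in opposite directions, PIF4 and HSP70-4 not among them. Of these 839 rose at 1 h and fell at 12 h (659.6 by chance) and 1367 fell and then rose (1296.1 by chance). In ino80 1317 rose at both times (1098.4 by chance, odds ratio 1.45, exact p = 1.55e-19) and 823 fell (625.8 by chance, odds ratio 1.55, exact p = 6.96e-21), and 1662 of 3802 had opposite directions. These were 550 that rose and then fell (564.8 by chance) and 1112 that fell and then rose (1217.1 by chance). Between the genotypes, 1207 genes were higher in ino80 at both times at 21 °C (488 by chance, odds ratio 5.08) and 1261 lower (470.5 by chance, odds ratio 6.52). At 27 °C these were 1441 (602.2 by chance, odds ratio 5.27) and 1104 (447.2 by chance, odds ratio 5.15). Of the interaction calls 2 were positive at both times (0.7 by chance, exact p = 0.141) and 6 negative (0.6 by chance, odds ratio 10.5, exact p = 4.26e-05), while 5 turned from positive to negative (0.9 by chance) and 4 from negative to positive (0.5 by chance).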

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

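Results were picked out here by a rule on the interaction test, which compares the response to warmth between the genotypes. The splits of the libraries, the scaling tests and the tests of RNA without poly(A) tails and of a linked segment were written after results were seen. The tests of a single library, of the insertion site neighbourhood and of the choice of the genes in Col were written before their own values were computed.

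At 1 h the interaction called 361 genes. Positive values were led by ATCG00350 (2.99), ATCG00270 (2.24), WRKY40 (1.55), CAF1a (1.43), DIC2 (1.38), ZAT10 (1.27), ARR15 (1.21) and CYP81D8 (1.14). WRKY40 was 1.07 TPM in ino80 at 21 °C (Col 9.88), so it could hardly fall there. Negative ones were led by AT1G12030 (-2.47), LSU1 (-1.52), ATSDI1 (-1.42), TRM13 (-1.29), NIA1 (-1.27), EXO (-0.99), AT5G12110 (-0.99) and GIS (-0.97). CYP81D8 stayed called without 9 of the 12 libraries and the others without each of them. Of the lists, flowering time had a median of 0.20, flavonoids -0.14 and root markers -0.12, and none held with an estimated correlation.

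At 12 h it called 147 genes. Positive values were led by APR1 (1.79), LOX2 (1.74), AT3G59930 (1.48), LSU3 (1.42), AOC1 (1.33), AT1G15125 (1.23), IMD1 (1.21) and APR2 (1.04), and negative ones by AT5G47590 (-1.65), AT1G47980 (-1.58), TIP2;3 (-1.26), NIA1 (-1.21), PELPK2 (-1.16), EMB3114 (-1.03), PHT4;1 (-1.03) and BGLU19 (-0.97). The number of fits without 1 of the 12 libraries that still called a gene was under 12 for LSU3 (2), AT1G15125 (3), IMD1 (8), TIP2;3 (5), NIA1 (10), PHT4;1 (3) and BGLU19 (2). Their values kept their sign and stayed between 1.15 and 1.63 for LSU3, between 1.01 and 1.39 for AT1G15125, between 0.99 and 1.37 for IMD1, between -1.45 and -1.02 for TIP2;3, between -1.35 and -0.98 for NIA1, between -1.16 and -0.86 for PHT4;1 and between -1.12 and -0.86 for BGLU19 over these fits. Heat shock genes had a median of 0.24 and seed maturation markers -0.21, and neither held with an estimated correlation.

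Splits of the libraries into other groups tested chance differences between single libraries. In each of the 8 comparisons of 3 against 3 libraries only the real split called any genes. The 10 splits are too few for a share under 0.05. For the interaction the additive effects of genotype and temperature, which widen the spread in other splits, were first removed from each gene. The interaction, which can do so too, was left in. Of 100 splits only the real one called as many as observed. The highest others called 2 at 1 h and 13 at 12 h. The test thus cannot exclude chance, or a difference shared by all libraries of a group.

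Chloroplast-encoded transcripts at 1 h were lower at 27 °C in Col and higher in ino80, a difference of 1.07 (SE 0.25) on the log2 scale. Carry-over of RNA without poly(A) tails would move mitochondrion-encoded transcripts alike, and their difference was 0.41 (SE 0.17), but the difference of the ratio of chloroplast to mitochondrion TPM was 0.65 (SE 0.25), more than 2 SE from 0, which speaks against it as the only cause. A single library was excluded, since the chloroplast difference was at least 0.91 without each library. Left are a genotype effect on the chloroplast response to warmth, the biological explanation, a carry-over that accounts for part of the difference, and an uneven capture of chloroplast RNA alone, which could differ between samples since the labels do not state how RNA was selected. An assay that does not select on tails would tell these apart.

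Genes changed by at least 1 log2 unit in the same direction in all 4 genotype comparisons numbered 101, 41 higher and 60 lower in ino80. A linked segment of other DNA that changes its own genes would group them, but 4 had another within 10 gene positions, against a permuted mean of 10 and 95th percentile of 17 (permutation p = 0.967), and 20 and 22 of as many temperature genes at 1 h and 12 h. That explanation had been worded more widely and was narrowed after its result was seen. A segment whose changed genes lie more than 10 positions apart was not tested. The insertion site neighbourhood, 50 gene positions on either side of INO80, held 1 of the 101 genes, OTP84. The permuted mean was 0.53 (95th percentile 2, permutation p = 0.413). A change of 1 or 2 genes there could not pass that percentile, so an effect of the insertion on genes near it is not excluded. OTP84 changed by -1.54 and -1.89 at 1 h and by -1.95 and -2 at 12 h, at 21 °C and 27 °C. The loss of INO80 is the biological explanation, but a second mutation acting on distant genes was not tested, as there is 1 mutant line, and another allele or a complemented line would settle it.

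The median response to warmth looked smaller in ino80 than in Col. At 1 h the mean ratio after rescaling by the median of ratios was 0.835. Rising and falling ratios share left-out libraries, so their spread cannot decide on scaling. The choice of the genes in Col remains a possible source at 1 h. With genes chosen in ino80 the ratio of Col to ino80 was 0.944 (rising 0.882, falling 1.006). At 12 h neither test could tell, with ratios of 0.903 and 1.028. A weaker response of ino80, the biological explanation, was thus not told apart from the choice of genes at 1 h. At 12 h it was not told apart from scaling or the choice of genes, and more replicates would be needed.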

How the results depend on the processing

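The alternatives were fixed before the data were examined, except the tests added after results were seen, which are the overlaps under median-of-ratios scaling and the interaction without chosen libraries. With an absolute log2 fold change of at least 1 the comparisons (temperature in Col, temperature in ino80, genotype at 21 °C, genotype at 27 °C, interaction) called 481, 413, 425, 435 and 55 genes at 1 h and 1572, 1390, 483, 596 and 31 at 12 h. Without each library in turn the interaction called 186 to 439 genes at 1 h and 54 to 127 at 12 h, and 68 at 12 h without the libraries least correlated with their group. In the same order, camera with an estimated correlation called 2, 2, 0, 0 and 0 lists at 1 h and 0, 0, 0, 0 and 0 at 12 h, and fry 8, 10, 9, 9 and 1 and 13, 12, 5, 8 and 0. The overlap of Col temperature calls between times had odds ratios of 3.21 for rising and 4.56 for falling genes at an absolute log2 fold change of at least 1, and that of positive interaction calls had 0. INO80 at 21 °C and 12 h was not called with a pseudocount of 5 (-0.28), with no filter on low TPM (-0.34), or without any 1 of its libraries (-0.31 without Col 21C replicate 1, -0.39 without Col 21C replicate 2, -0.32 without Col 21C replicate 3, -0.37 without ino80 21C replicate 1, -0.33 without ino80 21C replicate 2 and -0.33 without ino80 21C replicate 3). The interaction of PIF4 at 1 h, not called, changed sign without Col 21C replicate 1 (0.07), Col 27C replicate 2 (0.03) or ino80 21C replicate 2 (0.02). Over all 12 fits without 1 library it lay between -0.14 and 0.07. A part of the named genes was counted under the pseudocounts, filters, scalings, replicate block and robust eBayes. Of their 3209 values, 3189 kept their call and direction, 14 were no longer called and 6 gained a call. Of 2388 values without 1 library, 2337 kept both, 46 lost their call, 2 gained one and 3 changed sign, all of PIF4. Both counts leave out the interaction of CYP81D8 at 1 h and of LSU3, AT1G15125, IMD1, TIP2;3, PHT4;1 and BGLU19 at 12 h. Without 1 library these stayed called in 9, 2, 3, 8, 5, 3 and 2 of 12 fits. Of the 16 leading interaction genes at 12 h, 11 stayed called with the replicate block, 11 with no filter and 12 with robust eBayes. The threshold on the fold change and the fits of 2 groups alone were not applied to single genes. The cause was not tested for any of these moves. The planned fits on read counts by another tool were not run because the tables hold no counts. What the depth limits was not tested. In simulated data the interaction recovered 37.3 and 23.9 percent of 0.5 log2 changes at 1 h and 12 h.

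The temperature and genotype counts stayed within 1.5 times their value without each of their libraries, with 5395 to 6352, 4903 to 5450, 5776 to 6612 and 5939 to 6203 genes at 1 h and 10337 to 11051, 10003 to 10765, 4078 to 4895 and 4811 to 5309 at 12 h, in the order above. INO80 stayed called at 1 h, between -0.50 and -0.38 at 21 °C and between -0.52 and -0.41 at 27 °C, and at 12 h and 27 °C, between -0.70 and -0.44. Without organelle genes and the 1 h library with the fewest estimated fragments, Col 21C replicate 2, the interaction called 437 genes.

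Libraries of different groups carry the same replicate numbers. After group means were removed, the same-number pairs correlated across genes between -0.052 and 0.12 at 1 h (2 of 18 pairs over 0.1) and between -0.289 and 0.203 at 12 h (3 of 18), so the numbers do not pair. With the replicate block the interaction called 363 genes at 1 h and 93 at 12 h.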

Other observations

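The following tests were chosen after results were seen, on lists written at that point. Genes of the sulfur deficiency response fell with warmth at 1 h in Col (median -1.88, camera adjusted p = 7.63e-14, and adjusted p = 0.0213 with an estimated correlation) and in ino80 (median -2.63, camera adjusted p = 8.01e-17, and adjusted p = 0.0171 with an estimated correlation). Their interaction was negative at 1 h (median -0.24, camera adjusted p = 1.76e-06, and adjusted p = 0.061 with an estimated correlation) and positive at 12 h (median 1.03, camera adjusted p = 9.77e-17, and adjusted p = 0.0177 with an estimated correlation). That of jasmonate genes was positive at 12 h (median 0.55, camera adjusted p = 4.55e-12, and adjusted p = 0.0088 with an estimated correlation). Carbon starvation genes fell at 1 h in Col (median -0.72, camera adjusted p = 7.75e-05, and adjusted p = 0.0213 with an estimated correlation) and in ino80 (median -0.40, camera adjusted p = 0.00765, and adjusted p = 0.117 with an estimated correlation), with a positive interaction (median 0.29, camera adjusted p = 8.71e-05, and adjusted p = 0.0269 with an estimated correlation) in which 2 of 12 members were called. They rose at 12 h in Col (median 1.61, camera adjusted p = 2.02e-05, and adjusted p = 0.166 with an estimated correlation) and in ino80 (median 1.47, camera adjusted p = 1.28e-06, and adjusted p = 0.222 with an estimated correlation). Because the genes were picked from the same data, these values are not independent evidence.

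Early touch and wound genes were lower in ino80 at 21 °C and 1 h (median -0.81, camera adjusted p = 2.68e-06, and adjusted p = 0.114 with an estimated correlation), and their interaction was positive (median 0.91, camera adjusted p = 3.1e-18, and adjusted p = 0.0194 with an estimated correlation). They fell with warmth in Col (median -0.81, camera adjusted p = 0.000174, and adjusted p = 0.206 with an estimated correlation) and did not in ino80 (median 0.04, camera adjusted p = 0.418, and adjusted p = 0.672 with an estimated correlation), and the difference between genotypes at 27 °C and 1 h did not pass (median 0.06, camera adjusted p = 0.423, and adjusted p = 0.717 with an estimated correlation). The first 3 of these comparisons share the Col 21 °C libraries of 1 h, so they are not separate. An effect on those libraries alone was not tested. Chloroplast-encoded genes had a positive interaction at 1 h (median 0.87, camera adjusted p = 5.68e-33, and adjusted p = 0.0363 with an estimated correlation), and mitochondrion-encoded genes did not pass (median 0.14, camera adjusted p = 0.176, and adjusted p = 0.301 with an estimated correlation). In the jasmonate list at 1 h the interaction had a median of 0.03 and a mean of -0.10, which differ in sign (camera adjusted p = 0.0393, adjusted p = 0.176 with an estimated correlation, and 0.0856 with fry).

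Among the genes called in the interaction at both times were both nitrate reductase genes. NIA1 had -1.27 ± 0.11 at 1 h and -1.21 ± 0.21 at 12 h, and NIA2 -0.36 ± 0.08 and -0.86 ± 0.14 (log2 ± SE, n = 3 per group). ASN2 (-0.59 ± 0.08 and -0.71 ± 0.14), PAL2 (-0.50 ± 0.05 and -0.53 ± 0.10), CAX1 (-0.45 ± 0.09 and -0.76 ± 0.11) and ESM1 (-0.60 ± 0.11 and -0.51 ± 0.11) were negative at both times. LOX2 (-0.72 ± 0.08 and 1.74 ± 0.23), AOS (-0.35 ± 0.07 and 0.73 ± 0.14) and APR3 (-0.43 ± 0.10 and 1.01 ± 0.12) changed sign between the times.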
